A study of Mus musculus with 27 samples.

How the data were processed

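Total RNA of mouse olfactory mucosa was amplified by in vitro transcription with amino-allyl UTP and coupled to the dye Cy5, per the labels' protocols, and each array carried 1 labelled sample. The values are linear probe intensity values as deposited by the authors in a table of 29922 probes and 27 arrays. The scanner, the background method and the normalization are not given in the sources used here. From the values, the background had been subtracted, since between 1.45% and 3.93% of an array's values were at or below 0. The values of an array are whole numbers times a step of 0.912 to 1.07 (tolerance 0.05 of a step). How the authors set this step is not given in the sources used here. Between 36 and 80 probes per array lay at or above 99.5% of the highest value of the array and are called saturated. The noise limit of an array is 3 times the root mean square of its values below 0, and lay between 11.6 and 24.1. No fold is given for a probe that is below it on all arrays of both groups or saturated on nearly all.

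The title's number was read as the biological replicate and its letter as a repeat array of it. Arrays of 1 group and number had a median correlation of 0.962, against 0.949 for arrays of 1 group and letter with another number. The design text states that the open and occluded samples come from the same individuals. Equal numbers were read as the same individual, which gives 6 individuals. That equal numbers mark 1 mouse is a reading of the titles. The correlation of deviations from the group means was 0.516, -0.004 and 0.142 in the 3 pairs. The normal replicates are other mice, yet their deviations correlated with those of the same-numbered occluded replicates at 0.353, 0.067 and 0.0015. With the same-numbered open replicates they correlated at 0.394, 0.104 and 0.071. The values therefore do not settle the pairing by number. All groupings, tests, gene lists and the rule for named genes were set before the data were examined, except where a choice is said to have been made later.

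Values at or below 0 were set to the lowest positive value of the table (0.912) before log2. Array medians differed by 1.15 on the log2 scale, above the limit of 0.2 set beforehand, so the arrays were quantile normalized, and the 3 arrays of a biological replicate were averaged to 1 value, 9 in all. limma 3.58.1 in R 4.3.3, with statmod 1.5.0 and version 1.17.8 of data.table, fitted the 3 groups with the individual as a random block (consensus correlation 0.389) and tested the 3 comparisons for all probes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. No probe was left out for low signal. On data simulated with the real means and spread over 29922 probes, the test recovered 2.94%, 23.1% and 74.6% of probes changed by log2 0.5, 1 and 2 in occluded vs open, 0%, 2.78% and 47.1% in occluded vs normal and 1.35%, 3.64% and 38.0% in open vs normal. There were 4, 7 and 0 false calls in the 3 comparisons. The simulated probes varied independently of each other, and the normal mice had no deviation in common with same-numbered mice. These rates may therefore not carry over to the real data.

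Gene names came from an annotation table of the array that pairs 21020 probes with 1 symbol and 0 with several; 8902 probes are unnamed here. Of 16637 different symbols, 16633 were found among the symbols or synonyms of a RefSeq gene table of the GRCm38.p6 assembly, which was used for names alone, and 2728 were updated. For the 3566 genes with more than 1 probe, the probe with the highest mean stands for the gene. Gene lists were tested with limma's cameraPR with a preset correlation of 0.01, two-sided, with adjustment over 75 tests of 25 lists in 3 comparisons; 14 were called, and 5 of these were called with an estimated correlation. The rotation test fry found 0 lists that moved on balance and 4 whose genes changed in either direction. Lists with a call have a median, mean and test of 1 sign, which does not hold for all lists without a call.

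Genes were named by rule. In each comparison these were the 10 largest increases and the 10 largest decreases among named representative probes past the threshold, leaving out predicted transcripts (symbols of Gm or LOC with digits or ending in Rik) and accession-like symbols, with 1 sign in all pairs, or without overlap of the groups. Where fewer than 5 passed, the 5 with the smallest p in that direction were named as not passing. Omp, Gnal, Adcy3, Cnga2, S100a5, Kirrel2, Kirrel3, Lrrc3b and Hist2h2be, and up to 4 members with the smallest p of each called list, were named in addition. Efna5, Golm1, mMC019610, Spp1, Mmp13, Col1a2, Trpc2 and H2-M9 were named outside this rule, chosen after their values were seen. Alternatives covered the block, the averaging, the reading of the titles, the normalization, dim probes, the representative probe, the groups in the fit, the prior and each replicate left out. Probe sequences were not used here.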

Results

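Gene expression was measured in the olfactory mucosa of 25-day-old female FVB mice, the tissue that lines the back of the nasal cavity and holds the odor-sensing neurons. In unilateral naris occlusion 1 nostril is closed by cautery, so that the mucosa on that side receives little airborne odor while the side behind the open nostril is still ventilated. Mucosa from the occluded side and from the open side of the same mice was compared with mucosa from other mice that had received a sham cautery, here called normal. There were 3 biological replicates in each of the 3 groups and 3 arrays for each biological replicate, 27 arrays in all, with 29922 probes per array. The median intensity of an array lay between 123 and 274, and between 8.57% and 19.8% of its probes lay below its noise limit. The number of arrays and of mice limits the precision. Values below are log2 differences between groups of 3 biological replicates with their standard error (SE), unless stated otherwise.

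The first comparison asked how closing a nostril affected the mucosa behind it, with the open side of the same mice as the reference. Of 29922 probes, 66 passed an adjusted p of 0.05 in limma, 53 higher and 13 lower on the occluded side. There were 1852 with an unadjusted p under 0.05, against 1496 by chance. The genes that fell included 4 of 19 measured members of the list of odor-activity dependent neuronal genes. S100a5, which encodes a calcium-binding protein of olfactory neurons, fell by 2.07 ± 0.18 (SE) on the log2 scale (adjusted p = 0.0095). Its mean log2 intensity was 13.81 ± 0.44 (SD, n = 3) on the occluded side and 15.88 ± 0.07 (SD, n = 3) on the open side. On 5 of 9 open arrays the probe was saturated, so its level there is a lower limit. Kirrel2, a homophilic adhesion molecule of olfactory axons, fell by 1.89 ± 0.28 on the log2 scale (limma adjusted p = 0.048). Its call was lost in 11 of 20 alternatives, among them each of the 3 replicates left out. That of S100a5 was lost in 6 of 20.

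Pcp4l1, a relative of the calmodulin-binding protein Pcp4, fell by 1.32 ± 0.15 on the log2 scale (limma adjusted p = 0.017), and the protocadherin gene Pcdh10 fell by 1.18 ± 0.13 (adjusted p = 0.017). With p adjusted over the list alone, 5 members of the list fell and 3 rose. Lrrc3b was the additional one below 0 (-1.14 ± 0.25, adjusted p = 0.19 over all probes). The 3 that rose over the list alone were Kirrel3 (0.96 ± 0.15, adjusted p = 0.064 over all probes), the ephrin ligand gene Efna5 (0.88 ± 0.20, adjusted p = 0.22) and the cAMP phosphodiesterase gene Pde4a (0.72 ± 0.20, adjusted p = 0.42). Kirrel3 belongs to the same adhesion family as Kirrel2 and had the opposite sign. It passed in 9 of 20 alternatives. The histone gene H2bc21, listed on the array as Hist2h2be, differed by 0.37 ± 0.31 (adjusted p = 0.99). By camera the list lay lower on the occluded side, with a median log2 difference of -0.24 over 19 genes (camera adjusted p = 7.0e-08). Of these, 13 lay below 0 and 6 above. The rotation test fry did not call a movement of the list on balance (adjusted p = 0.061). It did find that genes of the list changed in either direction (fry adjusted p = 5.3e-08), a test chosen after the data were seen. The camera call held with an estimated correlation (adjusted p = 2.7e-07), in a range of 2.7e-10 to 0.00039 over the alternatives.

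**Figure D1:**
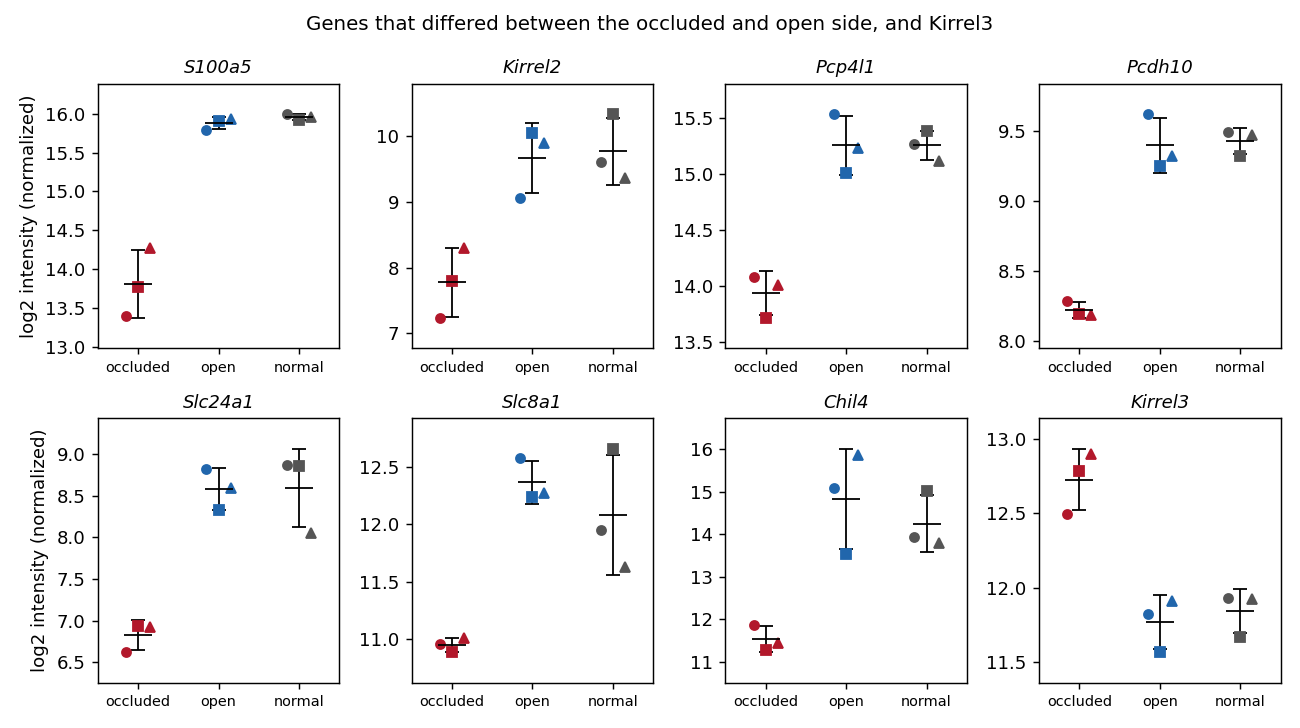
Normalized log2 intensity (vertical axis) of 8 genes in the 3 groups (horizontal axis). Each point is 1 biological replicate, the mean of its 3 arrays, with circles, squares and triangles for replicates 1, 2 and 3; horizontal lines and bars give the mean and SD of the 3. S100a5 lay at 13.81 on the occluded side and at 15.88 on the open side, and Kirrel3 is the only 1 of the 8 that lay higher on the occluded side (0.96).

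Further genes fell on the occluded side. Slc24a1, a potassium-dependent sodium-calcium exchanger, fell by 1.75 ± 0.22 on the log2 scale (adjusted p = 0.023). Slc8a1, a sodium-calcium exchanger, fell by 1.42 ± 0.21 (adjusted p = 0.046), and its other probes differed by -0.19, -1.42 and -1.45. Dleu7 fell by 1.37 ± 0.19 (adjusted p = 0.035), and by 0.77 with an offset of 50 added to the intensities before log2, a setting chosen after seeing the data. Pde6h, a subunit of the cone phosphodiesterase, lay lower on the occluded than on the open side (-1.01 ± 0.14, adjusted p = 0.035). Its mean log2 intensity was 7.07 on the occluded side, 7.06 in normal mucosa and 8.08 on the open side; the difference of open from normal did not pass. Chil4, a chitinase-like secreted protein, fell by 3.29 ± 0.45 on the log2 scale (adjusted p = 0.035). On 1 of 9 open arrays it was saturated, so its level there is a lower limit. A further probe of the gene differed by -3.18. Sptssb also passed, but it lay below the noise limit on all 9 occluded and on 6 of 9 open arrays, so no fold is given. Over the alternatives the call was lost in 11 of 20 for Slc8a1, 10 of 19 for Dleu7 and 8 of 20 for Slc24a1. It was lost in 9 of 20 for Chil4, 9 of 19 for Pde6h and 15 of 18 for Sptssb.

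Among representative probes of named genes, leaving out predicted transcripts and accession-like symbols, the largest increases on the occluded side were those of Afm, Lbx1, Dynap, Zfp157 and Slc36a3. Afm, which encodes a vitamin E-binding plasma protein, rose 10.3-fold (3.36 ± 0.31, limma adjusted p = 0.0099). Lbx1, a homeobox gene of muscle and spinal cord development, rose by 3.09 ± 0.32, with 4 of 9 open arrays below the noise limit. Dynap rose by 2.64 ± 0.29, the zinc finger gene Zfp157 by 2.57 ± 0.29 and the amino acid transporter gene Slc36a3 by 2.49 ± 0.29. The next were the splicing factor gene Luc7l (2.26 ± 0.33), the receptor gene Mrgprb3 (2.23 ± 0.22), the pseudouridine synthase gene Trub1 (1.80 ± 0.18), Ess2 (1.78 ± 0.21) and the otolith protein gene Oc90 (1.70 ± 0.24), with adjusted p between 0.010 and 0.043. With an offset of 50 added to the intensities before log2, a setting chosen after seeing the data, the difference was 2.12 for Afm, 1.35 for Lbx1, 1.51 for Dynap and 1.04 for Oc90. Further probes of these genes differed by -0.05 for Zfp157, by -0.01 for Trub1 and by 0.11 and 0.73 for Ess2. That of Zfp157 lay below the noise limit on more than 13 of 27 arrays, so its value says little. The probe with the smallest adjusted p belonged to Golm1, which was chosen after its values were seen. It rose by 3.14 ± 0.18 (adjusted p = 0.0012), while the brighter probe of the gene differed by -0.998 (adjusted p = 0.083). With a replicate left out, each of the 10 genes from Afm to Oc90 lost its call in at least 2 of 3 fits, and Zfp157, Luc7l, Ess2 and Oc90 in all 3. Of the 53 probes that rose, 38 had a gene symbol. For 11 of their genes a further probe could be read, with a median difference of 0.065 against 1.739 for the called probes. None of the 11 reached 50% of the called difference. The increases are thus readings of single probes and are not shown for the transcripts.

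The olfactory transduction list also holds other genes of olfactory neurons, such as Omp, Ebf1 and Lhx2. By camera it lay slightly higher on the occluded side, with a median log2 difference of 0.23 over 23 measured genes (camera adjusted p = 0.0040, and adjusted p = 0.0042 with an estimated correlation). Of these, 15 lay above 0 and 8 below, and fry did not call a movement on balance (adjusted p = 0.14). Its test of change in either direction, chosen after the data were seen, gave a call (fry adjusted p = 0.0021). None of the 23 passed on its own and 7 had an unadjusted p under 0.05. The smallest p-values were those of Ric8b, a chaperone of the olfactory G protein (0.86 ± 0.24, limma adjusted p = 0.41), of Pde4a, of the calcium exchanger gene Slc24a4 (0.55 ± 0.17, adjusted p = 0.52) and of the channel subunit gene Cnga2 (0.53 ± 0.17, adjusted p = 0.55), which was saturated on 3 occluded arrays. With a replicate left out, Ric8b ranged from 0.48 to 1.08. Adenylyl cyclase gene Adcy3 differed by 0.34 ± 0.13 (limma adjusted p = 0.71) and the G protein gene Gnal by 0.47 ± 0.19 (adjusted p = 0.76). Omp, the marker of mature olfactory neurons, was saturated on 9 of 9 occluded and 8 of 9 open arrays and gives no fold. The list call was lost without replicate 2 (adjusted p = 0.083) and without replicate 3 (adjusted p = 0.19), in a range of 9.6e-05 to 0.19 over the alternatives.

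The 689 olfactory receptor genes, the odor receptors of which each neuron uses 1, had a median log2 difference of 0.11, with 435 above 0 (camera adjusted p = 0.023, but adjusted p = 0.74 with an estimated correlation). None passed on its own in limma. There were 75 that had an unadjusted p under 0.05, and of these 60 lay higher and 15 lower on the occluded side. The smallest p-values were those of Olfr31 (1.05 ± 0.18, limma adjusted p = 0.081), Olfr1161 (1.32 ± 0.23, adjusted p = 0.092), Olfr825 (-0.69 ± 0.14, adjusted p = 0.16) and Olfr370 (0.94 ± 0.20, adjusted p = 0.18). Receptors share sequence, so a probe can read related ones and each is uncertain. Without replicate 3 the median was 0.02, the test turned to lower and the adjusted p was 0.88, in a range of 0.00015 to 0.88 over the alternatives. Without replicate 2 the median was 0.20, and it was 0.07 with a floor at 16 and 0.05 with an offset of 50 before log2, both chosen after seeing the data. The call was also lost without normalization (median 0.06, adjusted p = 0.096) and with median centring (adjusted p = 0.11).

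4 further lists lay lower on the occluded side with the preset correlation and lost the call with an estimated one. Genes of Bowman's glands and nasal secretion had a median of -0.24 over 20 genes (camera adjusted p = 0.0024, adjusted p = 0.27 with an estimated correlation). The range over the alternatives was 3.0e-33 to 0.27. Of these genes Chil4 fell, over all probes and adjusted over the list alone. The immunoglobulin transporter gene Pigr (-0.82 ± 0.23, adjusted p = 0.42), Odam (2.34 ± 1.16, adjusted p = 0.87) and the odorant-binding protein gene Obp2a (-1.66 ± 0.88, adjusted p = 0.90) did not pass. Obp2a was saturated on 3 of 9 occluded and 6 of 9 open arrays. With a replicate left out, Obp2a ranged from -2.505 to -0.67, Pigr from -1.13 to -0.45 and Odam from 1.55 to 3.69. Immediate early genes, which are switched on by recent cell activity, had a median of -0.06 and a mean of -0.35 over 20 genes (adjusted p = 0.0065, adjusted p = 0.21 with an estimated correlation, range 0.00035 to 0.23). Their smallest p-values were those of Fos (-1.12 ± 0.32, limma adjusted p = 0.43, with a further probe at 0.31), Nr4a1 (-1.44 ± 0.42, adjusted p = 0.46), Fosb (-1.15 ± 0.34, adjusted p = 0.47) and Nr4a2 (-0.55 ± 0.20, adjusted p = 0.66, with a further probe at 0.15). Immune and inflammation genes had a median of -0.17 over 34 genes (adjusted p = 0.00086, adjusted p = 0.31 with an estimated correlation, range 1.6e-06 to 0.31). Adjusted over the list alone, 1 member rose and 2 fell. The smallest p-values were those of Cxcl2 (-1.64 ± 0.25, limma adjusted p = 0.054, 6 of 9 occluded arrays below the noise limit), Cxcl1 (-1.28 ± 0.26, adjusted p = 0.16), Ms4a1 (0.73 ± 0.19, adjusted p = 0.33) and Il1b (-0.54 ± 0.17, adjusted p = 0.55). Over the alternatives the Cxcl2 difference lay between -1.84 and -0.57, so its size is uncertain. Horizontal basal cell genes, markers of the reserve stem cells, had a median of -0.17 over 12 genes (camera adjusted p = 0.021, adjusted p = 0.31 with an estimated correlation, range 0.0021 to 0.88). Krt14 (-0.38 ± 0.15), Krt17 (-0.36 ± 0.16), Trp63 (-0.27 ± 0.15) and Krt5 (-0.32 ± 0.21) had the smallest p-values and none passed. Without replicate 3 the median was -0.09 for Bowman's gland genes (adjusted p = 0.26), -0.12 for immediate early genes (adjusted p = 0.23), -0.02 for immune genes (adjusted p = 0.20) and -0.03 for horizontal basal genes (adjusted p = 0.88). Without replicate 2 it was -0.18 for immediate early, -0.31 for immune and -0.30 for horizontal basal genes, and without replicate 1 it was -0.25 for immediate early and -0.36 for immune genes. The immediate early median was -0.16 without normalization, -0.11 with median centring, -0.14 with the median of arrays and -0.0087 without the dimmest 30% or 50% of probes. The immune median was -0.10 without these probes, -0.11 with a floor at 16 and -0.09 with an offset of 50 before log2, and that of Bowman's gland genes was -0.13 with the offset. The floor and the offset were chosen after seeing the data. The adjusted p of the immediate early list was 0.13 without replicate 2, 0.056 without the dimmest 50% of probes and 0.0502 with the mean of all probes of a gene. That of the horizontal basal list was 0.074 with the pair as a fixed replicate block and 0.11 with median centring.

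The remaining lists gave no call between the sides. Immature olfactory neuron genes had a median of -0.16 over 19 genes (camera adjusted p = 0.090), basal progenitor and cell cycle genes -0.13 (adjusted p = 0.28), mature olfactory neuron genes 0.00022 (adjusted p = 0.24), sustentacular cell genes -0.04 (adjusted p = 0.89) and xenobiotic and odorant metabolism genes -0.02, with a test direction of higher (adjusted p = 0.58). Hypoxia genes had a median of -0.12 (adjusted p = 0.33), oxidative stress genes -0.00016 and apoptosis genes -0.02, both with a test direction of higher (adjusted p = 0.99), ion and water transport genes -0.05 (adjusted p = 0.83) and vomeronasal receptors -0.01 (adjusted p = 0.85). Among markers of other cell types, the medians were 0.08 for vomeronasal neurons (adjusted p = 0.40), 0.06 for olfactory bulb or brain (adjusted p = 0.37), 0.03 for skeletal muscle, with a test direction of lower (adjusted p = 0.96), 0.02 for respiratory epithelium (adjusted p = 0.89), -0.01 for bone and cartilage (adjusted p = 0.41), -0.03 for glia (adjusted p = 0.60), -0.03 for blood (adjusted p = 0.89) and -0.10 for endothelium (adjusted p = 0.36). The single measured trace amine receptor was not tested as a list.

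The count of 66 depends on how the pairs enter the fit. It was 0 with the pair as a fixed replicate block on the 6 values of both sides (1705 with an unadjusted p under 0.05), 2 with the number as a fixed block over all 9 values and 3 with no replicate block. It was 0 without normalization between arrays (714 with an unadjusted p under 0.05), and leaving out replicate 1, 2 or 3 of both sides gave 0, 35 and 6. Of the genes named above as fallen, by their representative probe, S100a5 and Chil4 alone passed in any of these 3 fits.

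**Figure D2:**
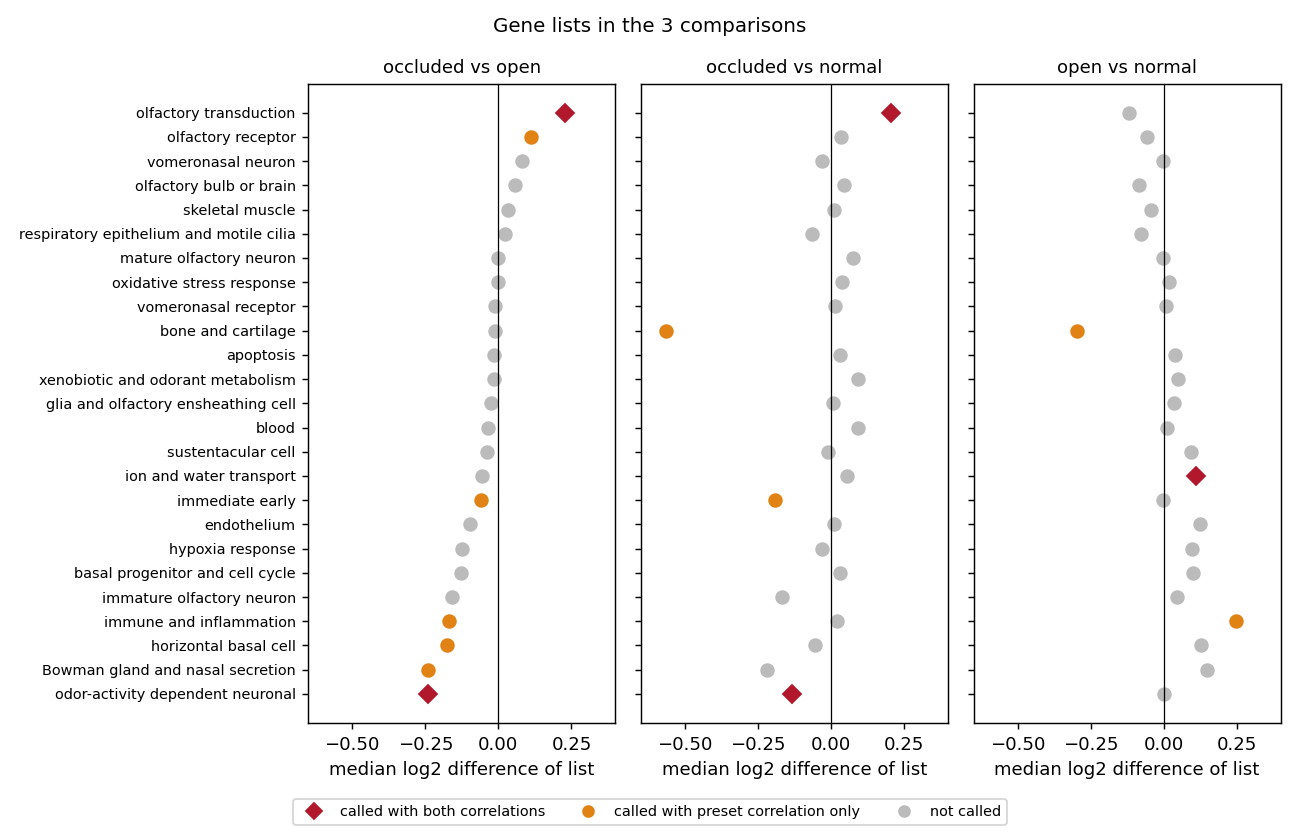
Median log2 difference (horizontal axis) of the representative probes of 25 gene lists (vertical axis) in the 3 comparisons. Diamonds mark lists called with the preset and with the estimated correlation, orange circles those called with the preset correlation alone, grey circles those not called; the odor-activity dependent list lay at -0.24 in occluded vs open and at -0.14 in occluded vs normal.

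The second comparison set the occluded side against mucosa of the sham-treated mice, which are other individuals. The odor-activity dependent list again lay lower by camera, with a median of -0.14 over 19 genes (camera adjusted p = 8.2e-06, and adjusted p = 2.2e-05 with an estimated correlation). The range over the alternatives was 4.8e-10 to 0.018. Of the 19, 11 lay below 0 and 8 above, and fry did not call a movement on balance (adjusted p = 0.16). Its test of change in either direction, chosen after the data were seen, gave a call (fry adjusted p = 4.1e-09). The median was -0.04 without normal replicate 2 and without normalization, and -0.21 without occluded replicate 1, normal replicate 1 or normal replicate 3 and with the median of arrays. It was -0.31 without the dimmest 50% of probes and -0.08 with an offset of 50 added before log2, a setting chosen after seeing the data. Adjusted over the list alone 4 members fell and 2 rose, while over all probes no member passed. S100a5 differed by -2.15 ± 0.23 (limma adjusted p = 0.066, saturated on 7 of 9 normal arrays, so its level there is a lower limit), Kirrel2 by -1.99 ± 0.36 (adjusted p = 0.28), Pcp4l1 by -1.32 ± 0.19 (adjusted p = 0.19) and Pcdh10 by -1.21 ± 0.17 (adjusted p = 0.18). Kirrel3 differed by 0.88 ± 0.20 (adjusted p = 0.53), Lrrc3b by -0.74 ± 0.31 and H2bc21 by 1.05 ± 0.40 (both with an adjusted p of 1.0).

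Of 29922 probes 2 passed in limma, both higher on the occluded side, and both also passed against the open side. They were the Golm1 probe (2.76, adjusted p = 0.027) and a probe without a gene name here, mMC019610 (2.11, adjusted p = 0.048), both chosen after their values were seen. Fewer than 5 named genes passed in either direction. Among those that did not pass, the smallest p-values above 0 were those of Mrgprb3 (2.14 ± 0.28, adjusted p = 0.18), Trub1 (1.64 ± 0.23), the lipid kinase gene Pip5k1b (1.62 ± 0.23), Lbx1 (2.71 ± 0.41) and Afm (2.65 ± 0.40, adjusted p = 0.20). Below 0 they were S100a5, Pcdh10, Pcp4l1, Slc24a1 (-1.77 ± 0.28, adjusted p = 0.20) and Spag17, which lay below the noise limit on all 9 occluded and 7 of 9 normal arrays. Of the 66 probes called between the sides, 64 had the same sign here. The occluded replicates enter both comparisons, so this is not independent. An unadjusted p under 0.05 was found for 861 probes, against 1496 by chance. The count of 2 became 0 with the number as a fixed replicate block and when any of the occluded replicates, normal replicate 1 or normal replicate 2 was left out, and 1 without normal replicate 3.

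Olfactory transduction genes had a median of 0.20 over 23 genes against normal mucosa (camera adjusted p = 0.0031, adjusted p = 0.0038 with an estimated correlation, range 0.00013 to 0.094). The rotation test fry did not call a movement on balance (adjusted p = 0.24). Gnal (0.75 ± 0.24), Cngb1 (0.49 ± 0.23), Slc24a4 (0.43 ± 0.22) and Pde4a (0.50 ± 0.26) had the smallest p-values and none passed. A further Gnal probe differed by 0.09. Cnga2, saturated on 3 of 9 occluded arrays, differed by 0.34 ± 0.22 and Adcy3 by 0.17 ± 0.16, and Omp was saturated on all 9 arrays of both groups. Immediate early genes had a median of -0.19 over 20 genes (adjusted p = 0.0024, adjusted p = 0.17 with an estimated correlation, range 0.00014 to 0.17). Their smallest p-values were those of Nr4a1 (-1.52 ± 0.54), Fosb (-1.18 ± 0.43), Npas4 (-0.65 ± 0.30) and Fos (-0.87 ± 0.40, with a further probe at -0.01), none of which passed. Without occluded replicate 3 the adjusted p was 0.094 for transduction and 0.074 for immediate early genes, and for the latter it was 0.075 without occluded replicate 2, 0.059 without normal replicate 2 and 0.16 without the dimmest 50% of probes. The transduction median was 0.35 without occluded replicate 1 and 0.32 without normalization. The immediate early median was -0.08 without occluded replicate 3 or normal replicate 2, -0.40 without normal replicate 1 and -0.09 without the dimmest 30% or 50% of probes. Bone and cartilage genes had a median of -0.57 over 17 genes (adjusted p = 6.9e-05, adjusted p = 0.39 with an estimated correlation, range 1.5e-23 to 0.42). The smallest p-values were those of Phex (-0.62 ± 0.24), Dmp1 (-0.77 ± 0.38), Col10a1 (-1.75 ± 0.999) and Col9a1 (-0.63 ± 0.39), none of which passed. Normal replicate 2 had a mean of 11.61 over this list and the next normal replicate 10.14. Without normal replicate 2 the median was -0.14 and the adjusted p 0.42, and without occluded replicate 2 the median was -0.36. The other lists had adjusted p of 0.12 or more.

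The third comparison asked whether the open side of an occluded mouse differs from the mucosa of a sham-treated mouse. No probe passed in limma, and 477 of 29922 had an unadjusted p under 0.05, against 1496 by chance. With fewer than by chance the test was cautious here, so the lack of calls does not show that the groups are alike. S100a5 was saturated on 5 of 9 open and 7 of 9 normal arrays, so its difference here has no meaning. Kirrel2 differed by -0.10 ± 0.36 and Kirrel3 by -0.07 ± 0.20. These signs turned for Kirrel2 without open replicate 1 (0.27), without normal replicate 2 (0.19) and without normalization, and for Kirrel3 without open replicate 2 (0.04) and without normalization. Cnga2 differed by -0.18 ± 0.22, Adcy3 by -0.17 ± 0.16, Gnal by 0.29 ± 0.24, Lrrc3b by 0.41 ± 0.31 and H2bc21 by 0.68 ± 0.40. Omp was saturated on 8 of 9 open and 9 of 9 normal arrays. The named genes with the smallest p-values above 0 were Krtdap (2.04 ± 0.31), Pde6h (1.02 ± 0.18), Zfp354c, Fscn3 and Msmb, and those below 0 were Gabra6, Hells, Slc26a10, Zfp81 and Catsperb, all with an adjusted p of 1.0. Krtdap was below the noise limit on 3 of 9 normal arrays, and its difference lay between 0.56 and 2.37 over the alternatives. Apart from Krtdap and Pde6h, these lay below the noise limit on at least 4 of 9 arrays of each group. Of these only Slc26a10 has a bound above 1, at least 1.05-fold lower on the open side, and no fold is given for the others.

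Immune and inflammation genes lay higher on the open side than in normal mucosa, with a median of 0.25 over 34 genes (camera adjusted p = 5.8e-05, but adjusted p = 0.21 with an estimated correlation, range 9.5e-14 to 0.21). The chemokine genes Cxcl1 (1.10 ± 0.33) and Cxcl2 (0.88 ± 0.32), the B cell gene Ms4a1 (-0.67 ± 0.24) and Retnlg (0.88 ± 0.36) had the smallest p-values and none passed. Without open replicate 1 the adjusted p of the list was 0.0502 and the call was lost. Its median was 0.15 without open replicate 3 or normal replicate 1, 0.39 without normalization and 0.13 with an offset of 50 before log2, chosen after seeing the data. Ion and water transport genes had a median of 0.11 over 19 genes (adjusted p = 0.033, adjusted p = 0.044 with an estimated correlation, range 0.00058 to 0.25). The smallest p-values were those of Car4 (0.51 ± 0.25), Car12 (0.38 ± 0.28), Aqp4 (0.47 ± 0.35) and Slc4a4 (0.47 ± 0.39, with a further probe at -0.42), none of which passed. This call was lost in 10 of 24 alternatives, among them the number as a fixed replicate block (adjusted p = 0.0602) and leaving out open replicate 2 (0.13), open replicate 3 (0.25) or normal replicate 1 (0.073), 2 (0.14) or 3 (0.066). Its median was 0.24 without open replicate 1, 0.07 without normal replicate 1, 0.17 without normal replicate 3 and 0.22 without normalization. Bone and cartilage genes had a median of -0.30 (adjusted p = 0.00086, adjusted p = 0.54 with an estimated correlation, range 2.1e-24 to 0.69). The smallest p-values were those of Matn1, Matn3, Col2a1 (-1.70 ± 1.08) and Acan (-1.11 ± 0.76), none of which passed. With a replicate left out, Col2a1 ranged from -2.62 to -0.22 and Acan from -1.64 to -0.07. Matn1 and Matn3 were below the noise limit on 8 of 9 open arrays and on 3 and 6 of 9 normal arrays, so no difference is given. The log2 level of Matn1 was 11.79 in normal replicate 2, and 4.13 and 3.38 in normal replicates 1 and 3. Without normal replicate 2 that median was 0.0081 (adjusted p = 0.69), without open replicate 1 it was -0.03 (adjusted p = 0.21), and without normal replicate 1 it was -0.52. The other lists had adjusted p of 0.054 or more.

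Both comparisons with normal mucosa share the 3 normal replicates. Open vs normal had 0 calls in limma at 0.05 and at 0.1 (477 at an unadjusted p under 0.05), so no overlap of calls could arise. Their log2 differences correlated at 0.447 across 29922 probes, which are not independent replicates, while simulated unchanged groups gave 0.694 on average. The covariance was 0.0544 against a simulated 0.130, a difference of -0.0756. Both values lay below the lowest of 100 simulations (0.674 and 0.123), so the simulated groups do not describe these data. The simulation gave the normal mice no deviation in common with same-numbered mice. It therefore cannot tell whether the 2 comparisons are alike beyond the shared normal replicates. The 3 normal replicates cannot be split into parts of 2.

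**Figure D3:**
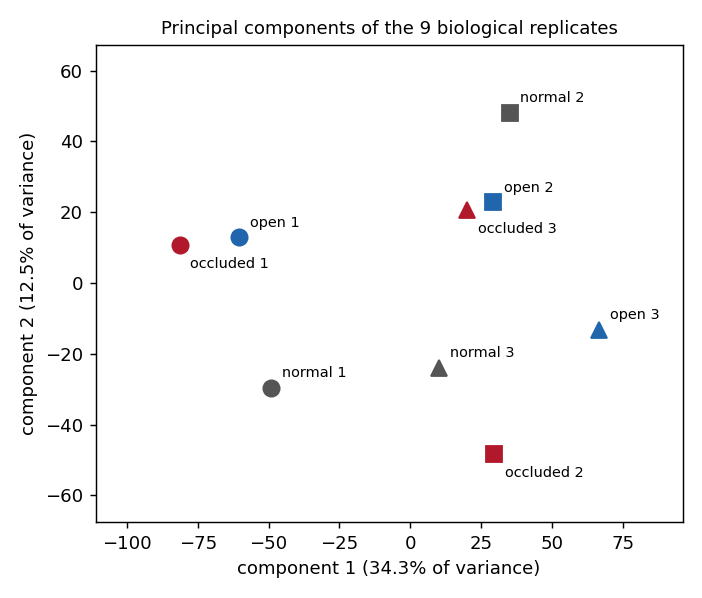
Scores of the 9 biological replicates on the first 2 principal components of the normalized log2 values, which carry 34.3% and 12.5% of the variance. Replicate 1 of all 3 groups lies apart from the other replicates on component 1, at -81.4 (occluded), -60.3 (open) and -49.2 (normal), although the normal mouse is another individual.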

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

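The tests of array measures below were chosen after the data were seen, and so were the tests in each paragraph of this part except the counts of other splits of the samples. Over 6 measures in 3 groups of 9 arrays, 3 arrays stood apart from the other arrays of their group, and chance gives about 1 such array in 20 groups; the arrays of a biological replicate are not independent. The noise limit of the third array of normal replicate 2 was 24.12, with the next at 15.18. That of the first array of occluded replicate 3 was 16.64, with the next at 14.39. The mean log2 value of the 53 probes called higher was 7.122 on the third array of open replicate 1, with the next open array at 6.777.

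Of the probes that passed between the occluded and the open side, the 53 higher and the 13 lower ones were examined apart. Among the 53, 11 genes had a further probe that lay below the noise limit on at most 13 of 27 arrays. Some of these were dim, with mean log2 levels from 4.19 (Cyp3a25) to 10.4 (Golm1). The median difference of these further probes was 0.06498, against 1.739 for the called probes, with 0 of 11 reaching a log2 difference of at least 50% of the called one. The deviations of the 53 probes between repeat arrays of 1 RNA had a median correlation of 0.2015, above the highest of 1000 random sets of like mean value (0.0676), while that of the 13 lower probes was 0.101, within the 95% range of their random sets (-0.0772 to 0.107). Among the 7 lists of other cell types with at least 3 markers of low level on the open side, the highest median was 0.0484 (bone and cartilage). Its SE of 0.356 is over 5 markers, not over mice. None of these medians came near the 1.739 of the called probes. With few markers and no spread over mice, this cannot exclude more cells of these types as the source. Glia and blood, with 2 and 1 such markers (highest median 0.2497, blood), stay open too. A probe-specific or hybridization signal is a candidate explanation for the increases, untested for the named genes without such a further probe. Among the 13 lower probes, 2 genes (Chil4 and Slc8a1) had further probes, with a median of -1.989, against -2.362 for their called probes. In 2 of 2 the further probes reached at least 50% of the called difference, but 2 genes are too few to decide for the 13. An effect of occlusion stays open for both sets.

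Bone and cartilage genes lay lower than in normal mucosa on both sides, calls that were lost with an estimated correlation (camera adjusted p = 0.39 for occluded and 0.54 for open). Of the 17 measured, 15 were above the noise limit on all occluded and open arrays, with 0 held by another list. The mean list difference was -0.709 ± 0.556 (SE) for occluded vs normal and -0.668 ± 0.581 for open vs normal. Without normal replicate 2 they were -0.1666 ± 0.179 and -0.1255 ± 0.246. In normal replicates 1, 2 and 3 the log2 level was 15.26, 15.96 and 15.73 for Spp1, 14.74, 15.27 and 14.80 for Mmp13, 13.42, 15.65 and 14.92 for Col1a2 and 8.53, 13.33 and 9.23 for Col2a1. The values go with a higher share of bone or cartilage in the tissue of normal replicate 2, a possible explanation that leaves biology of that mouse untested.

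The immune and inflammation list, called higher on the open side than in normal mucosa, lost its call with an estimated correlation (camera adjusted p = 0.21). Its mean list difference was 0.331 ± 0.178 (SE). Without open replicate 3, which had the highest mean, it was 0.2363 ± 0.170, so that a single open replicate as the cause can be neither shown nor excluded with this spread. Between same-numbered replicates the difference was 0.538, -0.128 and 0.584. The state of the open side in an occluded mouse, which the design names, stays open as an explanation.

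Of the 10 splits of the 6 samples of each comparison, 1 gave as many probes as the real 66 for occluded vs open (the real one; highest other 0), 1 as many as the real 2 for occluded vs normal (highest other 0) and 10 as many as the real 0 for open vs normal (highest other 0). 10 splits are too few for a share under 0.05. With equal numbers read as pairs, the 3 other splits that part all 3 pairs gave 0. They had 2205, 2679 and 1163 probes with an unadjusted p under 0.05, against 1848 for the real one. Splits that put replicate 1 of both groups together had 1012 to 3271 such probes in occluded vs open, 1236 to 2256 in occluded vs normal (861 for the real one) and 1441 to 3803 in open vs normal (482 for the real one). The other splits that part replicate 1, the real one aside, had 830 to 2679, 949 to 2062 and 680 to 1717. These ranges overlap and come from few splits, so the counts alone neither show nor exclude a structure of the samples along replicate 1. In both comparisons with normal the real split had the fewest such probes of its 10 splits. On principal component 1, replicate 1 of all 3 groups did lie apart (-81.4 occluded, -60.3 open and -49.2 normal). The source of this was not tested. In these splits the block correlation was estimated on a subset of the probes; with all probes the real counts were 1852, 861 and 477.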

How the results depend on the processing

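The tests with a floor at 16, an offset of 50, single arrays left out and the number as a block for occluded vs open were chosen after seeing the data. The signal over background and the saturated probes limit what can be seen at both ends of the scale. For occluded vs open, the main count of 66 became 3 with no replicate block (3 shared with the main calls), 0 with a fixed replicate block on the 6 paired values, 2 with a fixed block by number over all 9 values, 14 with the 2 groups alone, 141 with each array as a value, 805 with the title's letter as the replicate, 0 without normalization, 37 with median centring, 102 with a trend and robust prior and 109 without the second array of occluded replicate 2. For occluded vs normal, the count of 2 became 117 with each array as a value, 803 with the letter, 0 without normalization, 13 and 16 without the dimmest 30% and 50% of probes, 0 with 1 probe per gene, 0 with the 2 groups alone, 26 with a trend and robust prior, 5 with the median of arrays, 0 with the fixed replicate block, 0 with the floor at 16 and 18 with the offset of 50. For open vs normal, 0 became 121 with the letter and stayed 0 in the other 21 alternatives. The letter treats repeat arrays as replicates and so has a smaller spread; for the other moves the cause was not tested. Leaving out replicates gave 0 to 35 probes for occluded vs open, 0 to 1 for occluded vs normal and 0 throughout for open vs normal.

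The 14 list calls became 22 with each array as a value or with the letter, and 5 with an estimated correlation. The odor-activity dependent list kept its call in all 22 alternatives for occluded vs open and all 24 for occluded vs normal (adjusted p at most 0.00039 and 0.018). Apart from the horizontal basal list and the ion and water transport list, the block ended no list call. The sign turned without normalization for Kirrel3, open vs normal (0.01636) and Kirrel2, open vs normal (0.002725), and with the floor at 16 for Zfp354c, open vs normal (-0.001911). With a replicate left out, the medians of the olfactory receptor list ranged from 0.02115 to 0.1965. The difference ranged from -0.1096 to 0.02148 for S100a5, open vs normal (saturated on most of these arrays, so its sign has no meaning), from -0.2992 to 0.274 for Kirrel2, open vs normal, and from -0.1597 to 0.04488 for Kirrel3, open vs normal; the cause was not tested. Open vs normal had 0 calls at a threshold of 0.05 or 0.1, so the overlap of calls with occluded vs normal was fixed at 0.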

Other observations

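The tests of change in either direction with fry and the comparisons with random sets were chosen after the data were seen. In occluded vs open, 2 members of the vomeronasal neuron list lay higher over the list alone, the channel gene Trpc2 (0.84 ± 0.17, limma adjusted p = 0.16 over all probes) and H2-M9 (0.76 ± 0.21, adjusted p = 0.41), and fry found that genes of the list changed in either direction (adjusted p = 0.036) while camera gave no call (adjusted p = 0.40). The median difference of the 689 olfactory receptor genes (0.113) was set against 1000 random sets of other named genes matched on mean value. It lay above their 95% range (-0.018 to 0.021), which takes no account of the correlation between receptors. In open vs normal the same median was -0.0571, below the 95% range of the random sets (-0.017 to 0.019). In occluded vs normal it was 0.0347, just above that range (-0.010 to 0.032).

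Odam, Obp2a and Chil4 spanned a wide range within some groups, which was not tested for secretory genes in general. Odam had normalized intensities of 13595, 484 and 499 in the 3 occluded replicates, 893, 617 and 45.6 in the open ones and 2810, 5969 and 791 in the normal ones. Obp2a had 3241 in occluded replicate 1 and 65382 in occluded replicate 2, near the highest value of the arrays. Chil4 lay between 2470 and 3754 on the occluded side, between 11834 and 59128 on the open side and between 14165 and 33051 in normal mucosa.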
